A study of Mus musculus with 2 samples.

How the data were processed

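Total RNA of 2 cultures of growth-arrested CD1 mouse embryonic fibroblasts, 1 without and 1 with FGF2, was measured on Illumina bead arrays with 1 colour. Per the labels' protocols, 300 ng of RNA was amplified linearly with 6 h of in vitro transcription and labelled with Cy3. Per the submitters' processing notes, BeadStudio 1.0 was used. Each deposited array file gives, per the file headers, an average signal intensity, a bead standard deviation and a detection value for each of 24044 probes. The deposited intensities had been neither background-subtracted nor scaled: the lower quartile and the median of detected probes differed between the arrays by more than 0.05 log2, the limit set in advance. The bead column was about 3.6% of the signal. The files used here do not give the number of beads, so whether that column is a standard deviation or a standard error stays open, and it was taken as it stands. The deposited detection score runs from 0 to 1 and rises with brightness; 1 is detected.

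The authors' processed table of the same arrays holds intensities on a linear scale. Set against the array files, its control values equal the signal minus 139.2. Its FGF2 values equal the signal minus 131.5, multiplied by 1.054. The largest deviation from these lines was 0.095 intensity units, and the table gives a value exactly where the detection score was at least 0.99. Its medians were 288 for the control and 293 for the FGF2 array. The normalization method behind the factor is not given in the sources used here.

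Gene names rest on a match that the files do not state, and every name in the text depends on it. Numbers of at least 5 digits that follow 1 or 2 zeros in a probe's ID were looked up as NCBI gene IDs in the table of mouse genes (assembly GRCm38.p6). Of 9523 such probes, 8884 (93.3%) matched, whereas 32.3% of the neighbouring numbers are gene IDs. Probe IDs whose number has no leading zero matched in 10.7% of cases, against 10.5% of neighbouring numbers, and were left unnamed. The match was checked on the signals. Of 430 probes it assigned to olfactory and vomeronasal receptors, 2 were detected, and of 75 assigned to ribosomal proteins, 63 were. A further 12 probes were named by RefSeq accession. In all, 8896 probes of 7413 genes were named and 15148 were not; these count under their own ID. No coordinates are given because no genome build is named for the array.

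Signals were quantile normalized between the 2 arrays. A probe was called detected at a score of at least 0.99. Signals under the lowest detected signal of an array (191.7 and 193.1 after normalization) were set to it, and the log2 ratio of FGF2 over control was taken. A gene detected on both arrays has a fold; a gene detected on 1 has a bound. Each gene is represented by its brightest detected probe. With 1 array per group no test was run. The 26 gene lists hold 610 genes, of which 162 were detected under a name; the median of each list was placed among 10000 random lists of detected genes, matched in 10 bins of mean signal. Intervals of list medians are from 2000 bootstrap draws of the members. The middle 95% of random lists runs from the 2.5th to the 97.5th percentile. Genes named in the text were chosen by rule: the 15 largest folds in each direction among named genes detected on both arrays with a brighter signal of at least 509.6, the 5 largest bounds in each direction, up to 4 list members at least 1.5-fold apart, and 13 genes fixed in advance. Some genes that the rule takes are not reported here. Further list members outside this rule are also given, picked after their values were seen. Groups, lists, naming rule of the text and main settings were fixed before the data were examined; the match of probe IDs to genes was made afterwards.

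The procedure was tested on simulated data with 200 probes changed among 24044. Changes were planted only in named probes detected on both arrays with a mean signal above 2 times the background. Recovery of changes in dimmer genes was therefore not simulated. Planted 4-fold changes, a log2 of 2 or -2, came back with medians of 1.53 and -1.58, and 94% and 100% of them passed 2-fold. Planted 2-fold changes, a log2 of 1 or -1, came back at 0.77 and -0.82, and 10% and 24% passed, because background is part of the signal. None of the 8652 unchanged detected probes passed. The simulated noise of a log2 ratio had an SD of only 0.18, which all but excludes a pass at 2-fold. It held no difference between cultures or arrays, so this result says nothing about false calls in the real pair. Of 100 random lists of 12 genes, 7 fell outside the middle 95%. Alternatives covered the scaling, an added constant of 50, the authors' table, the detection level, brightness, the fold threshold and the choice of probe. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.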

Results

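Gene expression was measured in CD1 mouse embryonic fibroblasts, primary cells of the kind used as feeder layers for human embryonic stem cells. The cells had been growth-arrested with mitomycin C, a DNA crosslinker, and seeded at 55000 cells per square centimetre. They were kept for 24 h in human embryonic stem cell medium with serum replacement, either without FGF2 or with 40 ng/ml of FGF2, a growth factor that signals through receptor tyrosine kinases. Each condition was measured on 1 Illumina bead array, so there was 1 control array and 1 FGF2 array. Differences therefore had no replicate check, no p-value was computed, and every comparison describes this pair of arrays. Of 24044 probes, 8210 were detected on the control array (34.1%) and 8129 on the FGF2 array (33.8%). The median deposited signal of detected probes was 427 on the control array and 410 on the FGF2 array. Probes that were not detected had median signals of 141 and 133. These medians show how much of a dim probe's brightness was background. The combined bead error of a log2 ratio had a median of 0.076 and reached at most 0.14 among detected probes. A wider measure of error came from 312 pairs of probes of the same gene, in 247 genes, with both probes detected on both arrays. Their log2 ratios scattered with an SD of 0.18, or 0.24 over 375 pairs in 297 genes with bounds included. This SD pools changed and unchanged genes and can understate the error of genes with large folds. Among pairs with a probe at 2-fold or more, the difference was 1.37 in Etv1 and 0.84 in Acsl4. Between 2 probes of Ccnd1 it was 0.05. The number of arrays limits the precision beyond either of these errors.

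The comparison asked which transcripts of growth-arrested feeder fibroblasts differed after a day with FGF2. The highest ratios among bright named genes were those of Gch1, Errfi1 and Chrna1, and the lowest those of Ptn, Itga11 and Eln. Of the gene lists fixed in advance, those of FGF and ERK targets, of cytokines and chemokines, and of glycolysis had higher medians than random lists. Lists of matrix genes, matrix proteases, TGF-beta family ligands and secreted modulators, secreted growth factors, Wnt genes and interferon response genes had lower ones. In all, 9 of 17 lists with at least 5 detected members lay outside the middle 95% of random lists. For lists of unrelated genes 0.85 would by chance. Members of a list can vary together between any 2 cultures, so this excess does not point to FGF2. The secreted growth factor list was outside under only 6 of 10 alternative settings. Of these settings, the signals as deposited and median scaling differ by a constant and always give the same percentile. Each probe without a gene name is counted here as a gene. Among 8376 genes in this sense detected on at least 1 array, 115 were at least 2-fold higher with FGF2 and 155 at least 2-fold lower. With genes split by brightness into 5 bins, the middle 95% of log2 ratios ran from -1.12 to 1.0 in the brightest bin and from -0.33 to 0.34 in the dimmest. At 4-fold the counts were 16 and 28. Names rest on a match of numbers in the probe IDs to gene IDs, which the files do not state. Only 3220 of the 8376 were named genes, and 33 of these were at least 2-fold higher and 52 at least 2-fold lower. The other 5156 were unnamed probes, some of which may belong to the same gene. The deposited signals include background, which shrinks ratios of dim probes. In the authors' background-subtracted values, 290 genes were at least 2-fold higher and 389 at least 2-fold lower. These included all 115 of the higher genes and 153 of the 155 lower ones.

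**Figure D1:**
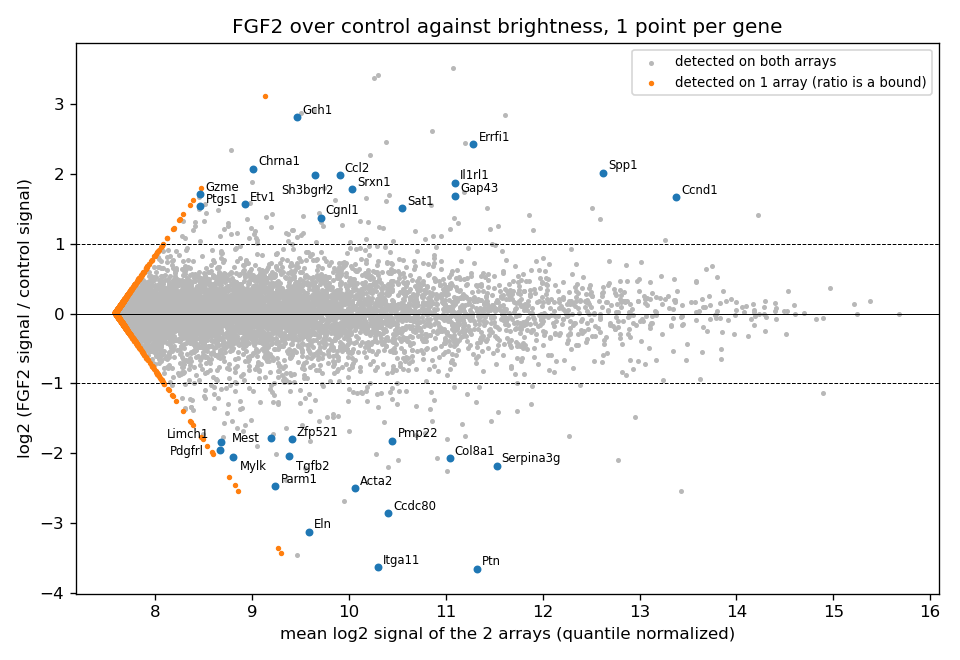
Each point is a named gene or a probe without a gene name. The x axis gives the mean log2 signal of both arrays and the y axis the log2 ratio of FGF2 over control signal. Dashed lines mark 2-fold; orange points were detected on 1 array and show bounds; blue points are the 15 named genes with the largest fold in each direction, from Gch1 (2.81) to Ptn (-3.65).

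Gch1, the first enzyme of tetrahydrobiopterin synthesis, had a log2 ratio of 2.81 (normalized signal 267 without and 1869 with FGF2). Its second probe, detected with FGF2 only, gave a bound of 0.50. Errfi1, a feedback inhibitor of the EGF receptor, was 5.37-fold higher, with a log2 ratio of 2.42 and a bead error of 0.072. Ccnd1, the cyclin that drives cells through G1, was 3.16-fold higher at high signals of 5993 and 18939. All 3 Ccnd1 probes lay between 1.66 and 1.92 on the log2 scale. Spp1 (osteopontin) was 4.03-fold higher, the monocyte chemokine Ccl2 3.95-fold, and Il1rl1, the receptor for interleukin 33, 3.65-fold. Chrna1, the acetylcholine receptor alpha subunit of muscle, was 4.20-fold higher and Gap43, a growth cone protein, 3.21-fold. The list also held Sh3bgrl2 (3.93-fold), the antioxidant enzyme Srxn1 (3.42-fold, with probes from 1.03 to 1.78 on the log2 scale), the protease Gzme (3.27-fold), the polyamine acetyltransferase Sat1 (2.83-fold) and the junction protein Cgnl1 (2.59-fold). The transcription factor gene Etv1 was 2.96-fold higher, but its other detected probe showed a log2 ratio of only 0.19 against 1.57. Ptgs1, the constitutive cyclooxygenase, was 2.89-fold higher. Among named genes detected with FGF2 only, Evi2a was at least 2.55-fold higher, and Itga6 (at least 1.99-fold), Nefm (at least 1.89-fold) and Ptgs2 (at least 1.80-fold) had bounds under 2-fold. In the authors' background-subtracted values several of these folds were over 1.5 times larger: 13.4 for Gch1, 8.39 for Gzme, 7.95 for Chrna1, 6.37 for Ptgs1 and 4.77 for Etv1. The bounds there were 6.19 for Evi2a, 4.31 for Itga6, 3.95 for Nefm and 3.67 for Ptgs2. The control values behind the folds of Gzme (62.2) and Ptgs1 (75.9) were near the lowest there, 58.7. Gzme also belongs to a family of similar granzyme genes, so its value is uncertain.

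Among named genes, the largest differences were in the other direction. Ptn (pleiotrophin), a secreted growth factor, was 12.5-fold lower with FGF2, with a normalized signal of 9079 without and 725 with it. Itga11, a collagen-binding integrin, was 12.4-fold lower on its brighter probe (4421 against 357), while its second probe, detected on the control array only, gave a bound of -0.31 on the log2 scale. Eln (elastin) was 8.70-fold lower, and Ccdc80, which codes for a secreted matrix-associated protein, was 7.21-fold lower. Acta2, the smooth muscle actin of contractile fibroblasts, was 5.64-fold lower (2548 against 452), and Mylk, the kinase that activates myosin, 4.12-fold lower. Tgfb2 was 4.12-fold lower and Col8a1 4.19-fold lower. Others were Parm1 (5.54-fold), the protease inhibitor Serpina3g (4.51-fold), Pdgfrl (3.88-fold), Limch1 (3.56-fold), the myelin protein gene Pmp22 (3.53-fold), Zfp521 (3.48-fold) and the imprinted gene Mest (3.44-fold). Serpina3g sits in a cluster of similar genes and is uncertain for that reason, as is Acta2, whose sequence is close to those of other actins. Genes detected on the control array only were Rgs4, a regulator of G protein signalling, at least 5.48-fold lower, and the pentraxin Ptx3, at least 5.03-fold lower. Further bounds were Adamts5 (at least 3.70-fold), Itgbl1 (at least 3.40-fold) and Ldb2 (at least 2.64-fold). With the authors' background-subtracted values the folds became 16.4 for Eln, 10.5 for Parm1, 9.33 for Pdgfrl, 9.20 for Mylk, 7.84 for Limch1 and 5.17 for Mest. Some FGF2 values there were near the lowest of 58.4: 72.4 for Pdgfrl, 82.2 for Limch1 and 85.5 for Mylk. Their folds therefore depend strongly on the background removed. The bounds there became at least 16.1-fold for Rgs4 and at least 14.6-fold for Ptx3, 9.03-fold for Itgbl1 and 6.53-fold for Ldb2, and -3.33 on the log2 scale for Adamts5.

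Genes known to respond to FGF and ERK signalling were compared next. Of the 30 genes on this list, 10 had a named probe and 7 were detected. Errfi1, Ccnd1 and Etv1 were at least 2-fold higher and none was 1.5-fold lower. Spred1, an inhibitor of ERK signalling detected with FGF2 only, stood at the list median with a bound of 0.58 on the log2 scale. Junb had a log2 ratio of 0.04, and Egr2 and Spred2 had bounds of 0.05 and 0.01. The list median of 0.58 lay above those of all 10000 random lists of matched brightness, and the median was 1.61 over members detected on both arrays and 1.39 in the authors' background-subtracted values. A bootstrap over members gave a 95% interval of 0.04 to 1.66 for the median. Percentiles and intervals of this kind describe the arrays and are no test of the treatment. Of FGF ligands, receptors and proteoglycans, 6 of 11 with a named probe were detected, and only the heparan sulphate proteoglycan Gpc1 differed by 1.5-fold or more (1.90-fold higher). Their median was 0.04, at the 61.5th percentile of random lists. Inhba, Tgfb1, Bmp4, Grem1, Tagln, Spry4, Dusp6 and Fgf2, 8 of 13 genes fixed for reporting in advance, had no probe named by the match and were not analysed here.

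Ligands and secreted modulators of the TGF-beta, activin and BMP pathways were lower as a group. Of 11 detected members, 7 were at least 1.5-fold lower, 4 of them at least 2-fold, and none was 1.5-fold higher. Beside Tgfb2, Tgfb3 was 2.77-fold lower (1581 against 571). Ltbp2, a matrix protein of the latent TGF-beta binding family, was 2.80-fold lower at signals of 13244 and 4730. Thbs1 (thrombospondin 1), an activator of latent TGF-beta, was 2.53-fold lower. Fst (follistatin), which binds activin, was 1.84-fold lower, and Ltbp1 had a log2 ratio of 0.27. The list median of -0.88 (interval -1.47 to -0.09), which is the value of Fst, lay below all random lists. Lefty1 was not detected on either array, with detection scores of 0.90 and 0.88. Of 8 detected target genes and SMAD pathway members, only Id3, a BMP target, was 1.5-fold lower (1.53-fold), and the median of -0.16 lay at the 5.7th percentile. With an added 50 in place of the floor it was -0.22, at the 2.39th percentile, and with detection at 0.05 the percentile was 1.49. Among brighter genes, those with a signal of at least 509.6 on either array, it was -0.34. Ccn1, another target gene of the list, had a log2 ratio of 0.30. The fold of Thbs1 was 5.43 in the authors' background-subtracted values.

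Extracellular matrix genes were lower on the FGF2 array in 14 of 15 detected cases. Of these, 8 were at least 1.5-fold lower and 4 at least 2-fold: Eln, Col8a1, Col1a1 and Col1a2. The type I collagen genes Col1a1 and Col1a2 were 3.38-fold and 2.46-fold lower. Col5a1, Pcolce and Loxl1 had log2 ratios of -0.96, -0.81 and -0.80, and Col3a1 stood at -0.57. Dcn (decorin), a small proteoglycan, was the exception at 0.42. The median was -0.60 (interval -1.30 to -0.44) and below all random lists. Of smooth muscle and myofibroblast genes, only 3 were detected under a name. Acta2 and Mylk were lower, as given above, whereas Cald1 (caldesmon) had a log2 ratio of 0.09. Among matrix proteases and their inhibitors, 4 of 7 were at least 1.5-fold lower and none 1.5-fold higher, with a median of -0.65, below all random lists. The interval over members, -1.25 to 0.17, crosses 0. Timp3, an inhibitor of metalloproteinases, was 2.38-fold lower, Adamts2, which processes procollagen, 1.70-fold, and Adamts4, an aggrecan-cleaving protease, 1.57-fold. For Adamts2 the fold was 2.67 in the authors' background-subtracted values, and the second probe of Timp3 gave a bound of -0.57 on the log2 scale, against -1.25 for the brighter one.

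Secreted growth factors of fibroblasts had a median of -0.24, at the 1.6th percentile, with an interval of -1.06 to 0.22 that crosses 0. Ptn and Igfbp3, an insulin-like growth factor binding protein (3.02-fold), were at least 2-fold lower, Igf1 was at least 1.63-fold lower, and 7 of 10 members stayed within 1.5-fold. The list did not stay outside the middle 95%: its percentile was 2.6 with the signals as deposited, 13.0 with genes detected on both arrays and 15.4 among brighter genes. Of Wnt ligands, antagonists and targets, 5 were detected and the median was -0.33, at the 1.0th percentile, with an interval of -1.68 to 0.31 that also crosses 0. Only the Wnt antagonist Sfrp1 was 1.5-fold lower (3.20-fold), and Wnt5a had a log2 ratio of 0.31. In the authors' background-subtracted values Igf1 was at least 3.15-fold, Igfbp3 4.88-fold and Sfrp1 5.42-fold lower.

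Cytokine and chemokine genes went both ways. Of 6 detected, Ccl2, Il1rl1, Ptgs2 and the chemokine Cx3cl1 (log2 ratio 0.67) were at least 1.5-fold higher. Il1rl1 is a receptor and Ptgs2 a cyclooxygenase, so the list median does not stand for chemokines alone, which went both ways. Cxcl14, a chemokine of epithelia and fibroblasts, was 1.97-fold lower, and Cxcl1 had a log2 ratio of -0.17. The median of 0.76 lay at the 99.99th percentile, with an interval of -0.58 to 1.93 that crosses 0, and was 1.45 in the authors' background-subtracted values. All 6 detected interferon response genes had ratios below 0, with a median of -0.51 (interval -1.04 to -0.07) at the 0.01th percentile. Irf9, part of the interferon-activated transcription complex, was 1.83-fold lower. Irf1 and Igtp stood at -0.55 and -0.46. Ifit3 and Oas1a, detected on the control array only, had bounds of -0.08 and -0.07, whose sign follows from that detection. In the authors' background-subtracted values the list median was -0.98, and the folds were 3.16 for Irf9 and 3.97 for Cxcl14.

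Genes of glycolysis and the hypoxia response were higher in 11 of 12 cases, mostly by less than 1.5-fold. Their median of 0.36 (interval 0.12 to 0.54) lay at the 99.97th percentile. Among the 11, Hk1 and Pfkp were detected with FGF2 only, which sets the sign of their bounds. Egln3, an oxygen-sensing prolyl hydroxylase, had a log2 ratio of 1.32 (4.69-fold higher in the authors' background-subtracted values), the pyruvate kinase gene Pkm was 1.69-fold higher, and Aldoa (aldolase) had a log2 ratio of 0.59. Eno1 and Ldha had log2 ratios of 0.50 and 0.28. All 14 detected members of the cell cycle list, which does not hold Ccnd1, stayed within 1.5-fold, among them Mki67 (-0.23), Pcna (0.30) and Plk1 (-0.04). Their median was -0.02, at the 34.3rd percentile. All 6 detected p53 targets, including Cdkn1a (-0.18) and Ccng1 (-0.23), and all 8 cholesterol biosynthesis genes, including Hmgcs1 (-0.34), stayed within 1.5-fold as well, with medians of -0.07 (26.1st percentile) and 0.14 (83.8th percentile). The cholesterol median was 0.23 with median scaling and 0.25 in the authors' background-subtracted values, and the p53 target median was -0.23 among brighter genes. The 6 detected HOX genes stayed within 1.5-fold with a median of -0.13 (8.49th percentile). Of 7 immediate early and stress genes, only Hsp90aa1, a cytosolic chaperone, passed 1.5-fold (1.68-fold higher), and the median was 0.04.

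**Figure D2:**
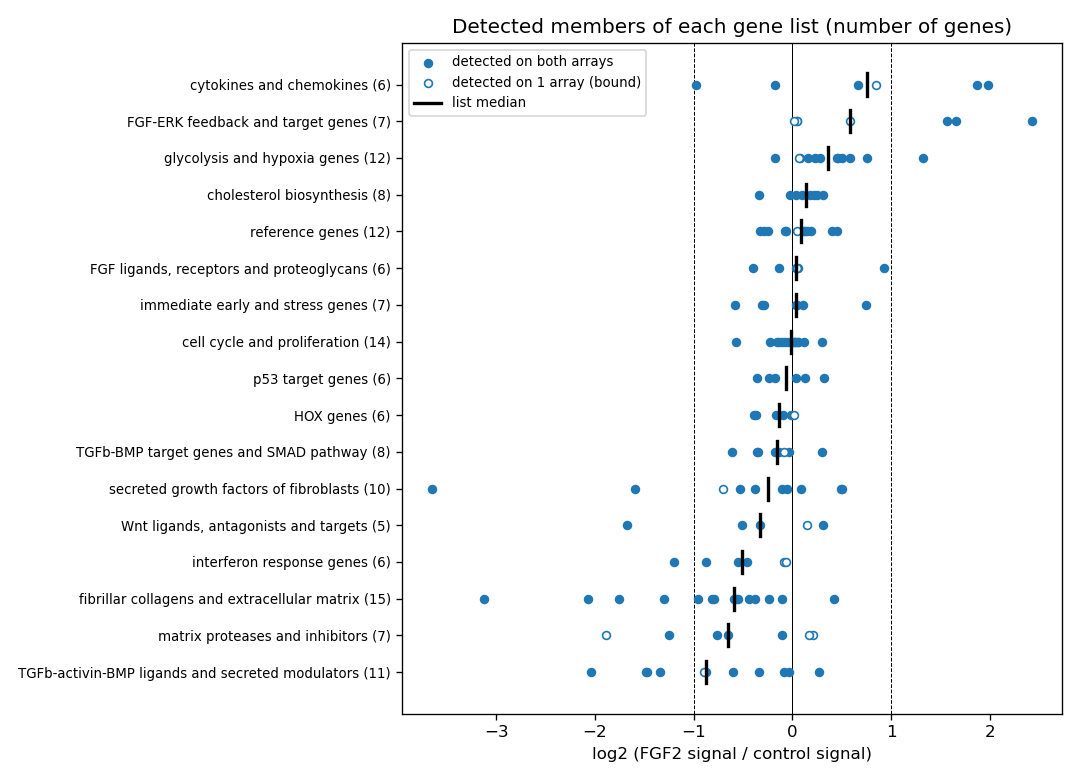
Each row is a gene list with at least 5 detected members (their number in brackets), and each point a gene's log2 ratio of FGF2 over control signal; open points are bounds and black bars list medians. Medians run from -0.88 for the list of TGF-beta, activin and BMP ligands and secreted modulators to 0.76 for the cytokine and chemokine list. Dashed lines mark 2-fold.

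Markers of other cell types that the cultures could hold were few and mostly not detected. Of 9 macrophage and blood markers with a named probe, Lyz2 (-0.12) and Hba-a1 (-0.04, a bound) were detected. Emcn (0.17) was detected among 4 endothelial markers. Among 4 epithelial markers, Krt18 was 1.88-fold higher, or 3.57-fold in the authors' background-subtracted values, and Cldn4 had a log2 ratio of 0.13. Of 11 neural and glial markers, Nes (nestin, 2.11-fold higher), Nefm (a bound, above) and Tubb3 (-0.17) were detected. Lpl had a bound of -0.59 on the log2 scale (at least 2.74-fold lower in the authors' background-subtracted values) and was the only detected gene among 4 adipocyte markers. Spp1 was higher and Col2a1 1.68-fold lower, and these were the detected ones of 6 bone and cartilage markers. Chrna1 was the only skeletal muscle marker with a named probe. Among fibroblast identity genes, S100a4 was 1.68-fold higher, while Cdh2 (-0.29) and Prrx1 (-0.55) were below 0. All 12 detected reference genes stayed within 1.5-fold, with a median of 0.08. Gapdh probes lay between 0.12 and 0.26, and Actb probes between -0.29 and -0.08. The direction of Actb depended on the scaling: its log2 ratio was 0.02 with median scaling and in the authors' background-subtracted values.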

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

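The counts of 115 higher and 155 lower genes stayed within 1.5 times of these values under the signals as deposited, median scaling, loess, an added 50, the mean of a gene's probes, detection at 0.05, detection on both arrays, the brightness filter, and counting probes. They moved with the authors' background-subtracted table (679 in all, 290 higher and 389 lower), at 1.5-fold (831, 364 and 467) and at 3-fold (87, 33 and 54). A filter at 3 times the bead column, added after seeing the data, says nothing about stability, because the highest bead error of 0.14 log2 lets no gene at 2-fold fail it. Also added, random lists of named genes alone left every list on its side of the middle 95%, and genes with a name alone, being fewer, gave 85, 33 and 52. Pairs with bounds, also added, gave a spread between probes of 0.24 against 0.18. The planned filter on bead standard errors was not run because the number of beads was not given. With 1 array per group no array could be left out. No scaling moved the median of all genes by more than 0.1 log2. Of the 68 genes chosen by the rule for named genes, the 47 at least 2-fold apart gave 282 values under 6 alternatives of scaling, offset, source and probe choice, 3 of them under 2-fold. Of 9 list medians outside the middle 95% of random lists, 8 stayed there under every alternative run for them, but the brightness filter left too few Wnt and interferon genes to be run; that of secreted growth factors did not with the signals as deposited, median scaling, genes detected on both arrays or brighter genes (percentiles over all alternatives 1.22 to 15.4). SMAD pathway and targets moved outside with an added 50 (percentile 2.39) and detection at 0.05 (1.49). List medians that moved under the authors' table were FGF and ERK targets 1.39, cytokines 1.45, interferon response -0.98, cholesterol 0.25 and glycolysis 0.50. Median scaling moved cholesterol to 0.23. FGF and ERK targets went to 1.61 with genes detected on both arrays and 1.66 with brighter genes. Among brighter genes the cytokine list gave 1.87, which is the ratio of the receptor gene Il1rl1. SMAD pathway and targets gave -0.34 there and p53 targets -0.23. Moves under the filters on detection and brightness follow from the members left, which were few. FGF and ERK targets kept Errfi1, Ccnd1, Etv1 and Junb on both arrays, and lost Junb among brighter genes. Brighter cytokine list members were Ccl2, Il1rl1 and Cxcl1, and brighter p53 targets Zmat3, Ccng1 and Cdkn1a. The cause of the other moves was not tested. Signal over background limits what can be seen of dim probes, whose folds are understated in the deposited signals. In the authors' table such folds rest on values near its lowest and depend strongly on the background removed.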

Other observations

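The 14 gene families examined here were defined by symbol after the lists' values had been seen, and the members named were picked by their values. Of 4 detected Ugt1a enzymes, which conjugate bilirubin and drugs to glucuronic acid, Ugt1a6a, Ugt1a6b and Ugt1a7c had log2 ratios of 1.05, 1.08 and 1.15 and Ugt1a5 of 0.03. These genes share exons, and a second probe of Ugt1a6b gave 0.01, so they do not count as separate observations. Gzmd, a neighbour of Gzme, was detected with FGF2 only (bound 0.71). Redox genes went apart: Srxn1 (1.78), Glrx (1.19) and Prdx6 (0.74, with a bound of 0.04 on a second probe) were higher, and the glutathione transferases Gstm1 (-0.92) and Gstm2 (-1.12) lower, among 18 detected with a median of 0.11. Of 19 histone H2A and H2B genes the median was -0.31, at the 0.06th percentile of matched random lists, with H2ac19 at -0.67 and the variant H2az1 at 0.46. Histone copies are near-identical, so their probes are not independent. Solute carriers (47 genes, median -0.02, or 0.02 with median scaling) had no member 1.5-fold apart. Under 5 other scalings, offsets or sources the Ugt1a, redox and histone medians kept their sign. Without names, the probes with the highest ratios on both arrays were scl37307.8.1_29-S (11.4-fold) and scl0003597.1_94-S (10.6-fold), and those with the lowest were scl48080.5_118-S (10.9-fold lower) and scl41467.7_13-S (6.44-fold lower).

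In the tests that follow, the uniform change in fibroblast RNA and the difference between cultures were written down after the values had been seen. The others were written before. Even so, the sets of ribosomal protein genes and of interferon genes outside the list were chosen after the lists' values had been seen. The set of ribosomal protein genes was corrected, to take in those of the small subunit, after a first value had been seen. The lower matrix genes and TGF-beta ligand and modulator genes were weighed first. A brightness-dependent trend between the arrays was weighed by loess. Under loess the matrix median was -0.62 (bootstrap 95% interval over members -1.34 to -0.46). The ligand and modulator median was -0.90 (-1.48 to -0.11). The quantile-normalized ratios held little trend to begin with: the medians of the 5 brightness bins ran from 0.007 to 0.021. Loess therefore had little to remove, and the nearly unchanged medians are no separate test. A smaller share of fibroblast RNA on the FGF2 array would lower every fibroblast gene by 1 factor. The log2 ratios of 18 matrix and fibroblast identity genes ran from -3.12 to 0.75, with an SD of 0.89. The SD was 0.18 between probes of a gene and 0.42 over all genes. These 18 genes thus did not share 1 ratio, but neither did detected genes at large, so the spread cannot decide on such a factor. Whether such a factor acts beside other differences stays open, because the SD over all genes is itself above 2 times that between probes. A difference between 2 cultures or arrays unrelated to FGF2 cannot be told apart from an effect of FGF2 with 1 array per group, and an effect of FGF2 on these genes stays a hypothesis.

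For the higher glycolysis genes, loess left the median at 0.36 (0.14 to 0.52), which for the same reason is no separate test of a brightness trend. A shift shared by bright housekeeping transcripts remains possible: the glycolysis median exceeded that of 60 ribosomal protein genes by 0.24, with an interval of -0.02 to 0.43 that reaches 0. Proteasome subunits (15 genes) had a median of 0.16 and complex I subunits (22 genes) one of 0.12. These medians stayed above 0 under every scaling run, and the excess over ribosomal genes went down to 0.13 with median scaling. Part of the glycolysis shift may therefore be shared with such transcripts.

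The interferon response list had 6 detected members, so the idea of a wider interferon-related shift was tested on 18 other genes chosen by symbol, such as Irgm2, Parp9, Ddx58 and genes of the major histocompatibility complex (H2-Ke6 is among them by its prefix alone). Their median was -0.29, below all 10000 random lists, with Irgm2 at -1.02, Parp9 at -0.88, H2-K1 at -0.35 and Ifitm1 at 0.04. Several of the H2 genes are similar in sequence, so their probes may not be independent and the percentile may overstate the shift. The median stayed below 0 under every scaling run. This is consistent with lower interferon-related expression in the FGF2 culture, which a single pair of arrays cannot tie to FGF2. Only 2 of the 18 were at least 1.5-fold lower.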
